A study of Mus musculus with 2 samples.

How the data were processed

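The samples were 2 biological replicates of neural tube tissue from mouse embryos at embryonic day 13.5, immunoprecipitated with an antibody against H3K27ac, per the labels. Each replicate was a separate tissue sample of the same strain with both sexes pooled, and the library fragments were selected between 300 and 500 bp, per the labels. All 4 peak lists are narrowPeak tables on mm10, which is GRCm38, per the deposited text files that accompany the samples. Those files say that each replicate's list was derived from that replicate's alignment and 1 further file, which they do not describe, that the pooled list was derived from all of these together, and that the replicated list was derived from the pooled list and both replicate lists. A control experiment is named by the labels, and no control values were analysed here. The aligner, the peak caller, its threshold and the rule for a replicated peak are not given in the sources used here. The deposited signal value of a peak is the authors' enrichment score, on a scale the files do not state. The deposited −log10 p-value and −log10 q-value of a peak are those of the authors. The lowest −log10 p in a list was between 2.005 and 2.042, and 83.2% of replicate 1's, 83.5% of replicate 2's and 99.2% of replicated peaks had a −log10 q of at least 2. No read counts are in these files, so read depth is unknown, and a missing peak does not show that the mark was absent. Shares of peaks have exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only.

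Peaks on chromosomes 1 to 19, X and Y were used, and 13 to 15 per list on other sequences were left out. Peaks did not overlap others of their own list. Peaks were compared with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Replicate overlap needed at least 1 bp, and its chance level came from 1000 random circular shifts of a list along each chromosome, leaving out the leading assembly gap, with a one-sided permutation test. The pairs for Spearman's rho took each peak of replicate 1 with the peak of replicate 2 that it overlapped most. Gene models were the protein-coding genes of the basic GENCODE M21 annotation (21911 genes with a symbol), and sequence came from GRCm38.p6. A promoter peak lay within 1 kb of any start of a gene by at least 1 bp. Distal peaks were more than 1 kb from every such start. Exon, intron and intergenic classes went by the peak's midpoint.

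Before the data were examined, 24 gene lists were fixed for the cell types, regions and pathways of the neural tube, for other tissues the sample could hold, and for olfactory receptors as a silent class. Some genes are in more than 1 list. The share of genes with a promoter peak in the replicated list was compared with all other protein-coding genes by a two-sided Fisher's exact test. The mean number of distal peaks within 50 kb of a gene's starts was compared with 100000 random lists of the same size in a two-sided permutation test, whose smallest p is 2e-05. Both were adjusted over the 24 lists (Benjamini-Hochberg, threshold 0.05). The genes are the units, and neighbouring genes can share a peak, so these p-values describe the libraries and not a population of embryos. CpG-matched tests drew genes from the same deciles of observed over expected CpG within 500 bp of the 5′ end of the gene. Hox coverage is the percent of bases under peaks from the first to the last base of a cluster's Hox genes. Means ± SD over the replicates' own lists have n = 2. Values given without replicate 1 come from replicate 2's own list, and those without replicate 2 from replicate 1's. Both lists are longer than the replicated list, so more than the replicate changes. No second group exists, so no test between groups was made.

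Domains joined replicated peaks that lay 12.5 kb or less apart and were ranked by peak-covered bases. Sequence words were matched on both strands in distal replicated peaks and in as many random windows outside all 4 lists, with no unknown base, the same length and a GC content within 1 percentage point. Such a window was found for 97.2% of the distal peaks, and chromosome Y was left out. The standard error is a jackknife over 20 chromosomes, and a word counted as above 1 past 2 standard errors. The words are short consensus strings, shared by many factors of a family.

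The genes named were set by a rule. From each list it takes the 3 with the highest signal value at a promoter peak of the replicated list, up to 3 in alphabetical order without a promoter peak in any of the 4 lists, and, olfactory receptors aside, those with one in only 1 replicate's own list. It adds every Hox gene, the 10 domains with most covered bases and the 10 distal peaks with the highest signal value. Other genes are said to be chosen after their values were seen, or are given as counts of distal peaks.

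The tests were tested on simulated data. In a pair of 20000 simulated peaks with a planted overlap of 60.6%, 60.9% overlapped, and 0 of 100 unrelated pairs of 5000 peaks gave p below 0.05. Over 21911 genes, the promoter test called 97.0% of simulated lists raised to a high share, 98.5% of lowered lists and left 96.1% of unchanged lists without a call. When promoter peaks depended on a confounder alone, it called 21 of 23 lists, and the matched test 0. The distal test called 83.3% of lists with 3 times the counts and left 96.4% of unchanged lists without a call. Simulated genes were independent of their neighbours, and simulated peaks were placed at random without clustering. The rates therefore do not cover lists whose genes share peaks, such as the Hox lists. A word planted at a ratio of 2.06 gave 1.98, and a word left alone 1.01.

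Alternatives fixed before the data were examined were other overlap rules, peaks with a −log10 q of at least 2, the 20000 peaks with the highest −log10 p, the pooled list, each replicate's own list, promoter windows of 500 bp and 2.5 kb, distal distances of 20 and 100 kb, CpG-matched genes, a background without olfactory and vomeronasal receptors, windows matched on length only and a joining distance of 5 kb. Those added after seeing the data were replicated peaks supported by both replicates, comprehensive gene models, genes matched on the number of neighbouring starts, and words counted outside repeats only.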

Results

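H3K27ac, a histone acetylation found at active promoters and enhancers, was mapped by ChIP-seq in the neural tube of mouse embryos at embryonic day 13.5. The neural tube is the embryonic structure that forms the brain and spinal cord. The sample description gives no level along the body axis, so which parts were dissected is unknown here. Tissue pooled from male and female embryos gave 2 biological replicates of a single group, so the data hold no second tissue or stage to compare with. The deposited files are peak lists on mouse build GRCm38 (mm10). Replicate 1's own list held 118833 peaks on chromosomes 1 to 19, X and Y, and replicate 2's held 104423. The pooled list, called on both replicates together, held 135305 peaks, and the replicated list held 73311. Peaks had a median length of 319 bp in replicate 1, 322 bp in replicate 2 and 627 bp in the replicated list, which covered 68.76 Mb. The sequencing depth is unknown from these files, so no depth stands behind a missing peak. The signal value given for a peak is the authors' own score on an unstated scale, and it ranks peaks within 1 list only.

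The first question was how far the replicates shared their peaks. Of replicate 1's peaks, 69657 (58.6%, exact 95% binomial interval 58.3% to 58.9%) overlapped a peak of replicate 2 by at least 1 bp. Of replicate 2's peaks, 71821 (68.8%, interval 68.5% to 69.1%) overlapped a peak of replicate 1. Both shares were far above chance placement. In 1000 circular shifts of the other list along each chromosome, 4.30% of replicate 1's peaks overlapped on average, 13.6-fold fewer than observed (one-sided permutation p = 0.001, the smallest the shifts can give, for either direction). The lists had 42.96 Mb in common, which was 65.3% of the bases of replicate 1's list and 73.5% of those of replicate 2's. Nearly all strong peaks met some peak of the other replicate. Of the 20000 peaks of each replicate with the highest −log10 p, 99.8% overlapped the other replicate's full list. Against only the 20000 strongest of the other list, 84.0% of replicate 1's and 85.2% of replicate 2's overlapped. Across 69657 overlapping pairs, Spearman's rho of the signal value was 0.647, and it lay between 0.598 and 0.809 on single chromosomes. This correlation is across peaks, which are not independent replicates. It was 0.806 when at least 50% of both peaks had to overlap.

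Peaks found in 1 replicate only were short, weak and mostly away from promoters. Replicate 1 had 49176 of them (41.4% of its list), with a median length of 229 bp and a median signal value of 3.04, against 489 bp and 4.31 for its shared peaks. Replicate 2 had 32602 (31.2%), with 221 bp and 3.04 against 436 bp and 4.05. In replicate 1, 5.19% of unshared peaks (exact 95% interval 4.999% to 5.393%) lay within 1 kb of a protein-coding start, against 22.7% of shared peaks. The same shares in replicate 2 were 5.36% (5.11% to 5.61%) and 22.5%.

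The replicated list consisted of pooled peaks: all 73311 had a pooled peak of the same position, which is 54.2% of the pooled list. A peak of each replicate met the 50% overlap rule (at least 50% of either peak's length) for 59080 of them (80.6%). A further 13507 met it in 1 replicate only and 724 in neither. The 14231 peaks without support in both replicates had a median signal value of 3.15 and a median length of 356 bp, against 4.50 and 760 bp for the rest. Of the pooled peaks outside the replicated list, 0 met the rule in both replicates.

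Over the whole replicated list, promoter peaks were longer and stronger at the median than distal peaks. In the replicated list, 14947 peaks (20.4%, exact 95% interval 20.1% to 20.7%) lay within 1 kb of an annotated start of a protein-coding gene, against 3.13% in 1000 circular shifts, a 6.51-fold excess (one-sided permutation p = 0.001, the smallest possible). Their median length was 1025 bp and their median signal value 9.09, against 571 bp and 3.75 for the 58364 distal peaks. Of all peaks, 2.82% were in exons outside promoters, 46.0% in introns and 30.8% between genes. Among the 20000 strongest peaks the promoter share was 50.9%, and there promoter peaks were the shorter ones (median 1424 bp against 1655 bp). In total 12204 of 21911 protein-coding genes (55.7%) had a promoter peak. The 2 replicates' own lists placed one at 12544 and 12340 genes, 11985 of them in common.

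Pan-neuronal, progenitor and proneural genes carried promoter peaks almost without exception. All 22 pan-neuronal genes had a promoter peak in the replicated list, led by Rbfox3 (signal value 35.2), which encodes the neuronal nuclear protein NeuN, Mapt (32.8), which encodes tau, and Tubb3 (32.1), which encodes neuronal beta-tubulin. All 16 progenitor and radial glia genes had one, led by the RNA-binding protein gene Msi1 (57.3), Zic1 (36.5) and the Notch effector Hes5 (24.9). The Zic1 peak also lay at a start of Zic4, and the Hes5 peak at a start of Pank4. Of 24 proneural and neurogenic genes, 22 had one, with Sox11 (47.7), Nhlh2 (45.7) and Sox4 (36.3) highest. The exceptions, Neurod4 and Neurog3, had no promoter peak in any of the 4 lists. All 20 housekeeping genes had one, among them Ywhaz (61.4), Actb (56.2) and Eef1a1 (42.3). Against 55.7% of other genes, these shares were higher (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over 24 lists: p = 2.41e-05 for pan-neuronal, 0.000375 for progenitor, 0.000555 for proneural and 4.16e-05 for housekeeping genes). The same 4 lists stayed higher against genes matched on promoter CpG content (adjusted permutation p = 0.00016, 0.0125, 0.000288 and 0.00498). The shares in the replicates' own lists were 91.7% for proneural genes and 100% for the others in both. These tests describe the genes of these 2 libraries.

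Regulators of the forebrain and midbrain were the reverse, in tissue whose level along the body axis the sample description does not give. Only 2 of 25 had a promoter peak in the replicated list: Bcl11b (37.1) and Satb2 (8.30). Dlx2, Dlx5 and Dlx6 had none in any list, and neither did Foxg1, Otx2, Six3 or Emx1, chosen here after their values were seen. The share of 8% was lower than that of other genes (Fisher's exact adjusted p = 1.39e-05), also against CpG-matched genes (adjusted permutation p = 0.00016). By contrast, 25 of 27 Hox genes of paralogue groups 1 to 9, which set position along the hindbrain and trunk, had one (92.6%, Fisher's exact adjusted p = 0.000163). The share for Hox groups 10 to 13 was 7 of 12 (58.3%, Fisher's exact adjusted p = 1.00).

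Regulators of single progenitor domains and neuron classes were less uniform. Of 28 dorsoventral domain regulators, 13 had a promoter peak, with Irx5 (16.0), Prdm8 (13.4) and Ascl1 (11.8) highest, and Arx, Atoh1 and Dbx1 without one in any list. This share of 46.4% did not differ from other genes (Fisher's exact adjusted p = 0.408), but it lay below the 77.8% of genes matched on promoter CpG content (adjusted permutation p = 0.00088). Of 34 regulators of spinal interneuron and motor neuron identity, 25 had one (73.5%, Fisher's exact adjusted p = 0.0514). Foxp1 (55.2), the dorsal interneuron factor Lbx1 (36.9) and Pou4f1 (20.7) were highest, and Gata3, Ptf1a and Sim1 had none in any list. Without replicate 1, that is in replicate 2's own list, the share was 79.4% and passed the threshold (Fisher's exact adjusted p = 0.0126). In the replicated list the share of 73.5% did not differ from the 75.2% of CpG-matched genes (adjusted permutation p = 0.985). Of 17 neurotransmitter genes, 10 had one: the glutamate transporter gene Slc17a6 (26.8) and the GABA genes Gad2 (22.2) and Slc32a1 (21.2) were highest, and Dbh, Slc17a7 and Slc18a2 had none (58.8%, Fisher's exact adjusted p = 1.00). Of 19 astrocyte and oligodendrocyte genes, 13 had one, led by Nfib (37.1), Slc1a2 (23.4) and Nfia (21.2), while Gfap, Mag and Mog had none (68.4%, Fisher's exact adjusted p = 0.408). That list passed the threshold only against CpG-matched genes (adjusted permutation p = 0.0492).

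Signalling pathway genes mostly had promoter peaks. The Notch list reached 19 of 20 genes (95%, Fisher's exact adjusted p = 0.000399), with Rbpj (33.5), Dll1 (26.9) and Hey1 (26.3) highest. The retinoic acid and FGF list reached 19 of 23 (82.6%, Fisher's exact adjusted p = 0.0179), with Spry2 (34.95), Fgfr2 (31.2) and Rara (27.6) highest and Aldh1a2, Cyp26a1 and Fgf8 without a peak. The Fgfr2 peak lay at the outer end of a gene model that runs from 130162451 to 133123350 on chromosome 7. A start of Ctbp2 lay there too, so the value cannot be assigned to Fgfr2 rather than Ctbp2. The Wnt and BMP list reached 23 of 29 (79.3%, Fisher's exact adjusted p = 0.0204), with Lrp6 (59.2), Axin2 (40.2) and Smad7 (37.9) highest and Bmp4, Bmp6 and Wnt3 without one. The neural crest and sensory ganglion list reached 19 of 22 (86.4%, Fisher's exact adjusted p = 0.00825), with Ntrk2 (24.8), Ntrk3 (21.8) and Pou4f1 (20.7) highest and Hand2, Phox2a and Phox2b without one. Against CpG-matched genes none of these 4 passed (adjusted permutation p = 0.0508, 0.0603, 0.649 and 0.177), and the Wnt and BMP share fell below the matched mean of 84.4%. Of 14 Hedgehog genes, 11 had one, led by Ptch1 (41.0), Cdon (25.9) and Gas1 (24.5), with Hhip without one (78.6%, Fisher's exact adjusted p = 0.136). Without replicate 1 the Hedgehog share was 92.9% (Fisher's exact adjusted p = 0.00862). In the replicated list the Hedgehog share lay below the 80.9% of CpG-matched genes, without a call.

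Most lists of other tissues had low shares of promoter peaks. The share was 1 of 18 for liver and gut genes and 1 of 18 for germline and pluripotency genes (Fisher's exact adjusted p = 4.16e-05 for each). The liver and gut peak, at Foxa3 (5.85), also lay at the start of Sympk. The germline peak was at Dazl (5.55). Afp, Alb, Apoa1, Ddx4, Dppa3 and Dppa4 had none in any list. Kidney, lung and epidermis genes had 2 of 18 (Fisher's exact adjusted p = 0.000375), Krt10 (20.4) and Foxj1 (6.03), and none at Cdh16, Cldn6 or Krt1. Only 3 of 1134 olfactory receptor genes had one, at Olfr94 (4.78), Olfr958 (3.15, not in replicate 2's own list) and Olfr571 (3.002), and Olfr1, Olfr10 and Olfr1000 had none. These 4 lists also lay below CpG-matched genes (adjusted permutation p between 0.00016 and 0.00603). Heart genes had 4 of 17 (Fisher's exact adjusted p = 0.0194), with Mef2c (12.8), Ryr2 (12.3) and Myh7 (5.87) highest and Gata4, Gata5 and Hand1 without a peak. Somite, muscle and cartilage genes had 8 of 25 (Fisher's exact adjusted p = 0.035), with Col2a1 (11.3), Tbx6 (8.66) and Foxc2 (6.46) highest and Acan, Acta1 and Actc1 without one. Endothelium, blood and microglia genes had 6 of 22 (Fisher's exact adjusted p = 0.0166), among them the endothelial genes Kdr (5.85) and Erg (4.62) and the microglial gene Csf1r (3.60), and none at Aif1, Cx3cr1 or Epor. The heart and endothelium shares did not differ from CpG-matched genes (adjusted permutation p = 0.166 and 0.301). The muscle share lost its call without replicate 1 (40.0%, Fisher's exact adjusted p = 0.138), and the endothelium share without replicate 2 (45.5%, adjusted p = 0.362). Of 14 meninges and fibroblast genes, 9 had one (64.3%, Fisher's exact adjusted p = 0.653), with Foxc1 (11.9), Ptgds (6.61) and Fn1 (6.24) highest and Aldh1a2, Lum and Tbx15 without one.

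**Figure D1:**
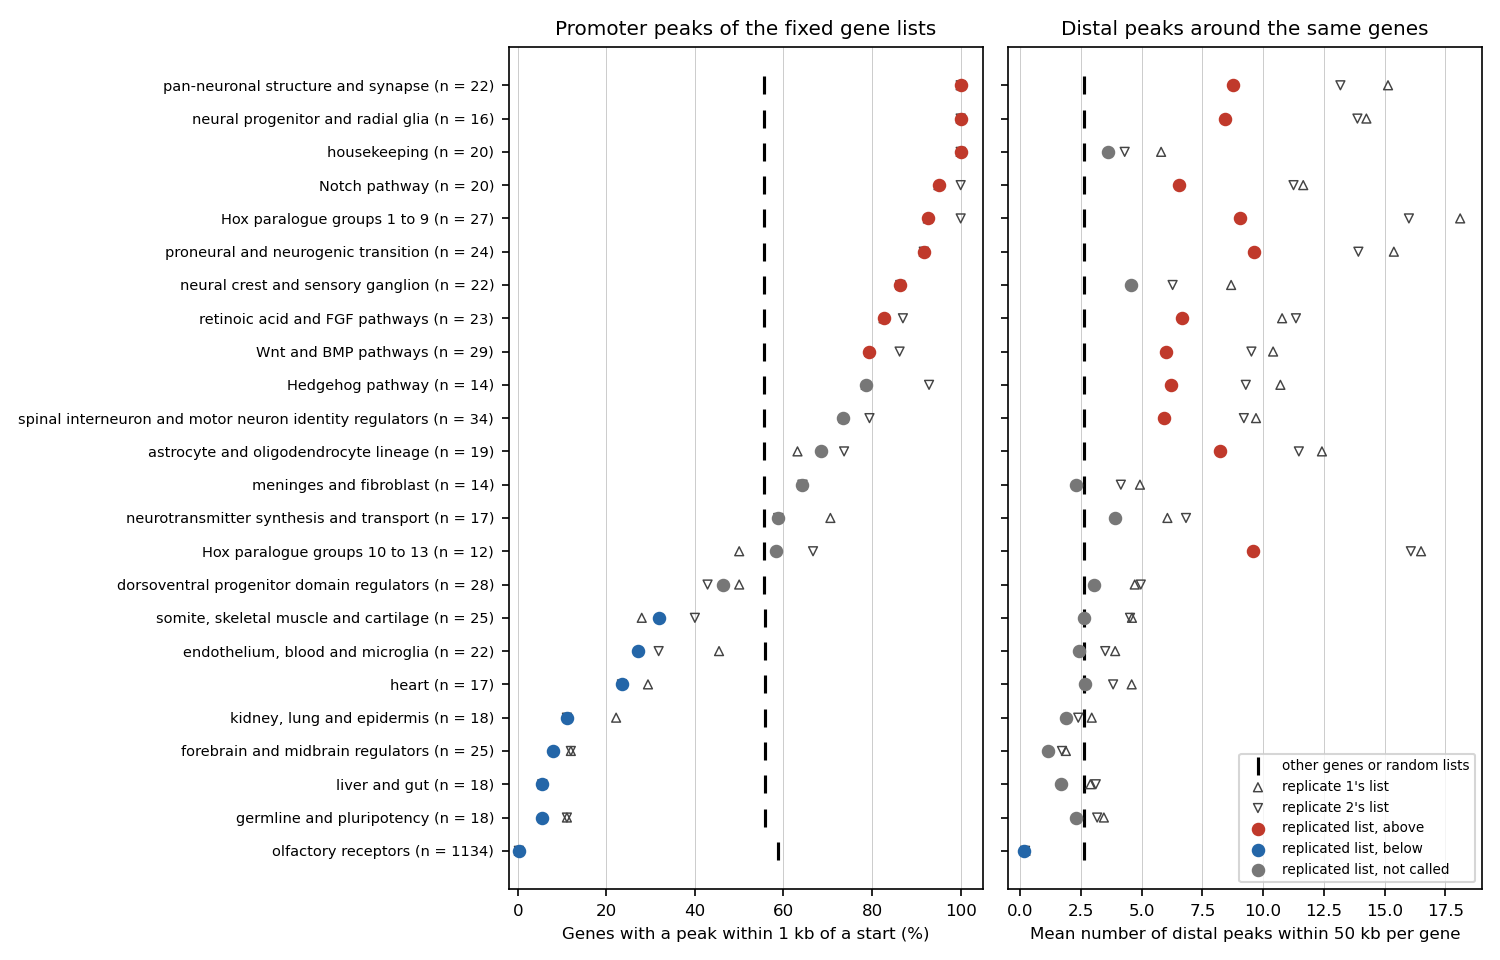
Left, the percent of each list's genes with a peak within 1 kb of a start, and right, the mean number of distal peaks within 50 kb per gene, for the replicated list (circles, coloured by the test), each replicate's own list (triangles) and other genes or random lists (bars, replicated list). The progenitor, proneural and pan-neuronal lists lie between 91.7% and 100% at the left, and the replicates' own lists, which hold more peaks, give higher distal means than the replicated list.

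Distal peaks were most numerous around proneural, Hox, pan-neuronal, progenitor and glial lineage genes. Random gene lists had a mean of 2.63 distal replicated peaks within 50 kb of a gene's starts. Proneural genes had 9.63, Hox groups 10 to 13 had 9.58, Hox groups 1 to 9 had 9.04, pan-neuronal genes 8.77, progenitor genes 8.44 and glial lineage genes 8.21. Spinal neuron regulators had 5.91, and the Notch, retinoic acid and FGF, Hedgehog, and Wnt and BMP lists 6.55, 6.65, 6.21 and 6.00. These 11 lists lay above random lists of the same size (permutation test with 100000 draws, two-sided, adjusted p between 0.00016 and 0.0321). Both Hox lists hold neighbouring genes of 4 clusters, whose windows count largely the same peaks again, such as 18 at each of Hoxc10 and Hoxc11. The random draws treat genes as separate, so the p-values of the Hox lists can be far too small. Olfactory receptors lay below, at 0.138 (permutation adjusted p = 0.00016). Single genes reached high numbers: 51 around Rbfox3, 38 around Ebf3, 26 around Foxp1 and 25 around Notch1. These are counts around all starts of a gene, so genes with starts far apart were searched over more sequence. Gene length and the number of starts were not matched. The other 12 lists, among them housekeeping genes (3.60, permutation adjusted p = 0.444) and dorsoventral regulators (3.04, adjusted p = 0.703), did not pass. With genes matched on the number of neighbouring starts, 10 of the 11 lists passed and the Hedgehog list did not (permutation adjusted p = 0.0626). Forebrain and midbrain regulators, at 1.16 (permutation adjusted p = 0.0626), lay below random lists without replicate 1 (adjusted p = 0.0383) or without replicate 2 (adjusted p = 0.0204). The neural crest list, at 4.55 (permutation adjusted p = 0.107), lay above them without replicate 2 (8.68, adjusted p = 0.0346). In the replicated list it did not pass against genes matched on neighbouring starts either (matched mean 2.875, permutation adjusted p = 0.232). In the replicates' own lists, which are longer, the proneural mean was 14.65 ± 1.03 (SD, n = 2) and the mean for Hox groups 1 to 9 was 17.06 ± 1.49 (SD, n = 2).

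Peaks were spread unevenly along the Hox clusters. Genes from group 2 or 3 to group 9 lay under near-continuous acetylation, which thinned towards the 5′ genes of groups 10 to 13 while replicated peaks covered 0% of the bodies of Hoxb1 and Hoxd1 at the 3′ end. In replicate 2's own list a short peak lay in each of these 2 bodies. Over groups 1 to 9, replicated peaks covered 96% of HoxA, 88.1% of HoxB, 95.4% of HoxC and 75.9% of HoxD. Over groups 10 to 13 they covered 55.6% of HoxA, 52.6% of HoxC and 49.0% of HoxD, and 0% of Hoxb13, the only such gene of HoxB. In the replicates' own lists the coverage of groups 10 to 13 was 48.6 ± 5.45% for HoxA, 43.6 ± 15.4% for HoxC and 44.7 ± 4.41% for HoxD (SD, n = 2), against 93.7 ± 2.99%, 92.2 ± 0.661% and 73.1 ± 0.352% for groups 1 to 9. The difference between the parts exceeded the spread between replicates in each of these clusters. In HoxC the parts overlap, since groups 1 to 9 begin at 102967443 and groups 10 to 13 end at 102971893, so most of Hoxc10 counts in both. The bodies of Hoxa10 (91.9%), Hoxd10 (88.2%) and Hoxc11 (95.2%) were still mostly covered. Those of Hoxa13, Hoxd12 and Hoxd13 were covered to 0%, and the remaining genes of these groups in HoxA, HoxC and HoxD lay between. For HoxC the replicates differed most: groups 10 to 13 were covered to 32.7% in replicate 1 and 54.5% in replicate 2.

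A single replicated peak of 79.5 kb, the longest in the list, ran over Hoxb3, Hoxb4, Hoxb5, Hoxb6, Hoxb7, Hoxb8 and Hoxb9 (chromosome 11, 96268032 to 96347536, signal value 59.8), and Hoxb2 lay in the next (46.5). In HoxA, a peak of 40.1 kb (chromosome 6, 52188135 to 52228206, 52.2) lay within 1 kb of starts of Hoxa3, Hoxa4, Hoxa5, Hoxa6, Hoxa7 and Hoxa9, and one of 16.2 kb of Hoxa1 and Hoxa2 (35.3). A peak of 23.7 kb in HoxC (chromosome 15, 102970084 to 102993768, 40.8) covered the starts of Hoxc8 and Hoxc9. Hoxc4, Hoxc5 and Hoxc6 had 24.5, 19.3 and 22.6. In HoxD the values were 57.2 at Hoxd3, 17.95 at Hoxd4, 51.6 at Hoxd8 and 20.4 at Hoxd9. The peak of 57.2 holds the outer ends of both gene models, at 74711927 for Hoxd3 and 74711929 for Hoxd4. Its value therefore cannot be assigned to Hoxd3 rather than Hoxd4. In groups 10 and 11 the values were 22.1 at Hoxa10, 13.1 at Hoxd10, 12.3 at Hoxc10, 9.31 at Hoxd11, 7.51 at Hoxa11 and 6.76 at Hoxc11. A peak over several genes carries a single value, which does not give the level at each gene under it. In replicate 1's own list Hoxa5 and Hoxa6 had 16.1 and Hoxa10 had 21.6. In replicate 2's own list Hoxa5 and Hoxa6 had 26.4 and Hoxa10 had 18.7. Hoxc13 had 3.12. Hoxa13, Hoxb13, Hoxd12 and Hoxd13 had no promoter peak in any list. Hoxb1, Hoxd1 and Hoxc12 had one in the pooled list and replicate 2's list only.

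**Figure D2:**
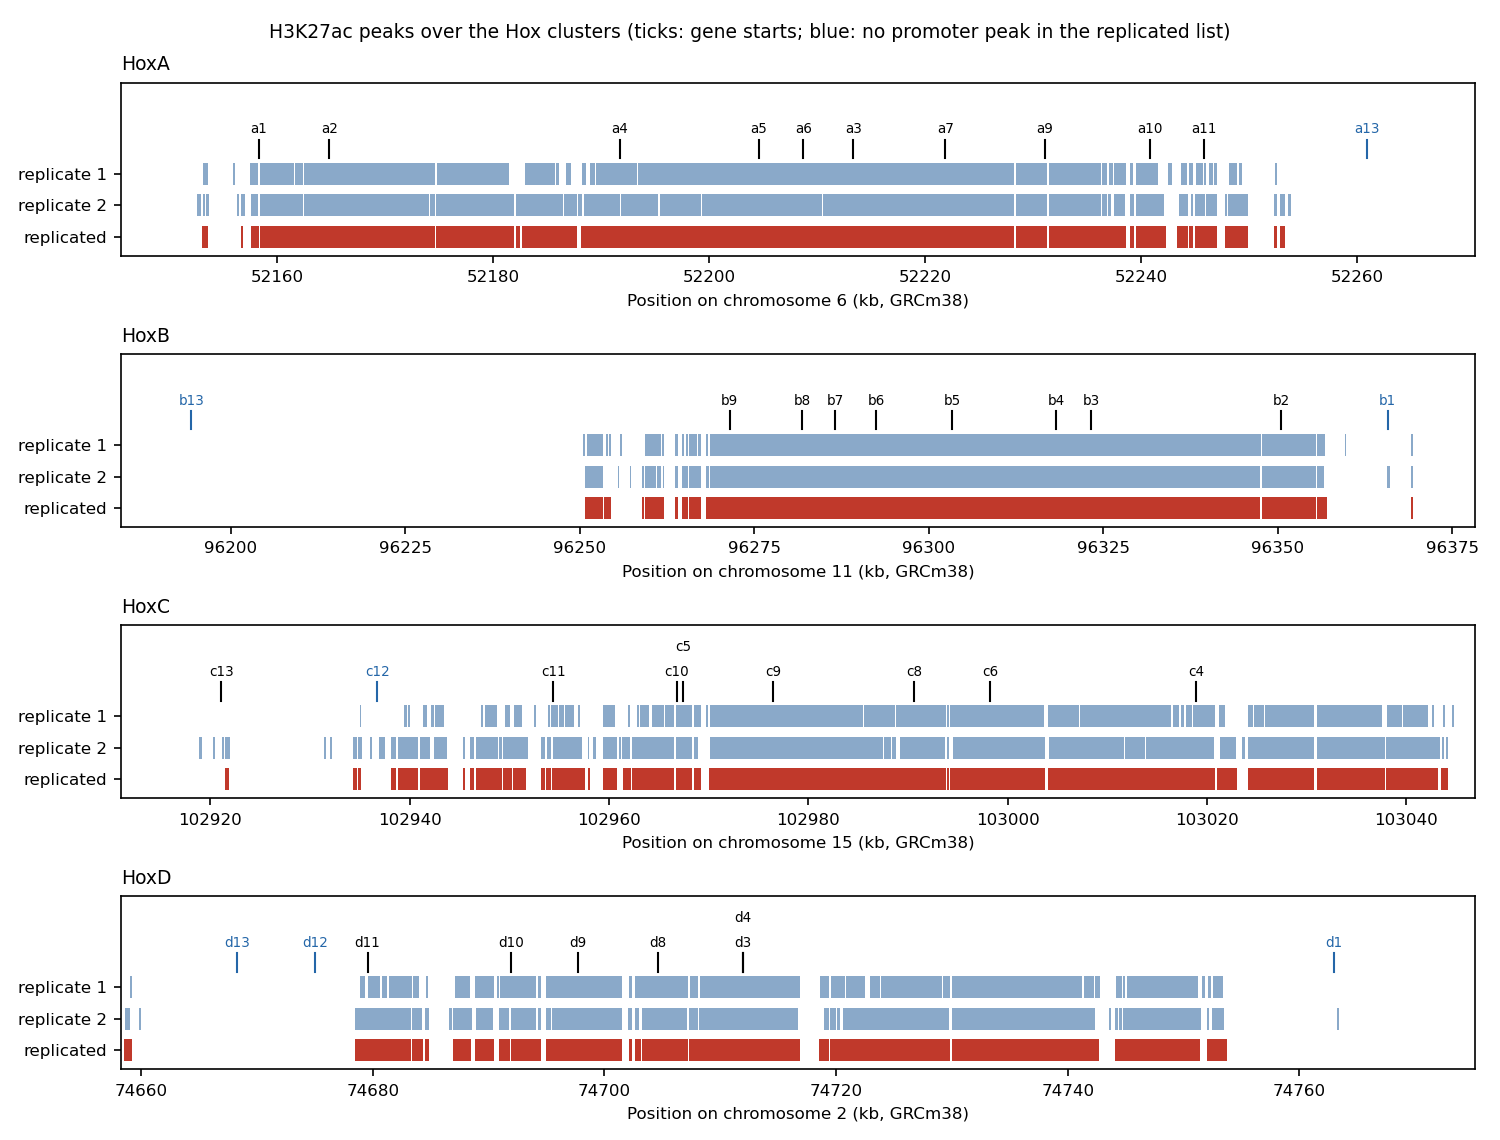
Peaks of replicate 1, replicate 2 and the replicated list (bars) over the 4 Hox clusters, by position in kb on GRCm38, with gene starts as ticks named by paralogue. Starts without a promoter peak in the replicated list (blue) lie at or next to the ends of the clusters, at Hoxa13, Hoxb13, Hoxb1, Hoxc12, Hoxd12, Hoxd13 and Hoxd1.

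Of the 470 genes in the lists other than olfactory receptors, 40 had a promoter peak in only 1 replicate's own list, 17 in replicate 1 and 23 in replicate 2, and 10 of the 40 were in the replicated list. Replicate 1 alone had peaks at the ventral regulators Foxa2, Olig2 and Mnx1, at Msx2, Sp8, Hesx1, Ddc and Tph2, at the vascular and blood genes Cdh5, Flt1, Tek and Gypa, and at Dcn, Tnnt2, Grhl3, Nphs1 and Tdgf1. Replicate 2 alone had peaks at Hoxb1, Hoxd1, Hoxc12 and Hoxc13, at the neural regulators Barhl1, Lhx2, Lhx3, Gsx1 and Dlx1, at the signalling genes Wnt1, Sfrp1, Heyl, Kif7, Scube2 and Rbp1, at Aqp4 and Cspg4, and at Pax1, Pax9, Tbx18, Postn, Sox7 and Esrrb. Those of the 40 in the replicated list had low values there, from 2.62 at Gsx1 to 4.05 at Aqp4 and Tbx18. Over all genes, 559 had a promoter peak in replicate 1's list only and 355 in replicate 2's only. Whether levels at these genes differed between replicates cannot be read from lists of called peaks.

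Distal peaks were richer than matched windows in several words bound by neural transcription factors, and also in many words outside the 12 chosen. The homeodomain word TAATTA occurred 0.292 times per kb in 56754 distal replicated peaks and 0.182 times per kb in random windows of the same length and GC content, a ratio of 1.60 (log2 ratio 0.68 ± 0.02, jackknife SE over 20 chromosomes). The POU word ATGCAAAT had a ratio of 1.48 (0.57 ± 0.05), the E-box CAGCTG 1.30 (0.38 ± 0.01), the Sox word ACAAAG 1.24 (0.31 ± 0.01) and the NFI word TTGGCA 1.15 (0.20 ± 0.01). RFX GTTGCC stood at 1.04. The words taken for other tissues were not all at 1: MEF2 CTATTT had 1.2 and GATA AGATAA 1.10, while HNF4 CAAAGTCCA had 0.93 and lay within 2 SE of 1. The E-box CATATG was depleted (0.806), and ETS CCGGAAG (1.04) and the NRSE core TTCAGCACC (0.903) lay within 2 SE of 1. Without replicate 1 the ETS word passed 2 SE (1.05), and without replicate 2 the HNF4 word fell below (0.838). Repeats made up 12.8% of peak bases and 28.4% of window bases, and outside repeats the RFX word stood at 1.0, within 2 SE, HNF4 fell below 1 (0.84) and CATATG rose to 0.932. In all, 8 of the 12 words were above 1 by more than 2 SE. Matching on length alone turned 4 of the 8 below 1, TAATTA (0.691), ATGCAAAT (0.772), AGATAA (0.668) and CTATTT (0.634), and left the Sox word within 2 SE of 1 (1.02). CAGCTG, GTTGCC and TTGGCA stayed above, and ETS CCGGAAG (2.31) and the NRSE core (1.24) passed 2 SE. Those windows had a GC content of 41.5%, against 49.1% in peaks.

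**Figure D3:**
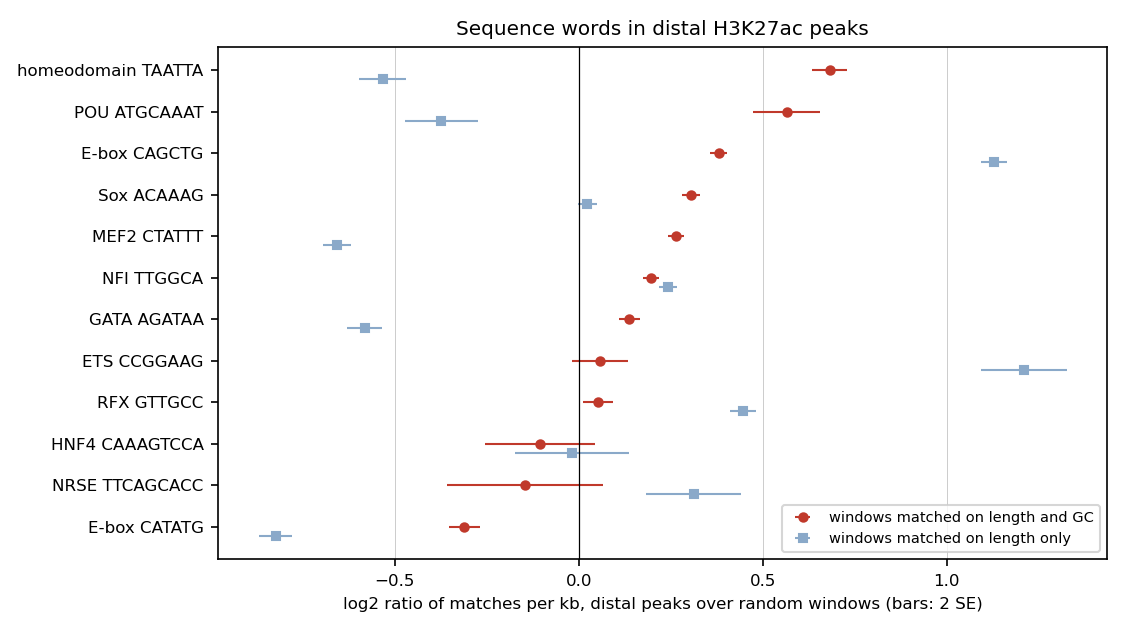
Log2 ratio of matches per kb in distal replicated peaks over random windows for 12 sequence words, with windows matched on length and GC content (circles) or on length only (squares), and bars of 2 SE from a jackknife over 20 chromosomes. TAATTA has the highest ratio of the circles, at 1.60, and lies below 1 among the squares.

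Joined into domains, the replicated peaks formed 27638 runs, the longest 497 kb. The domain with most peak-covered bases, 227 kb in 187 peaks, spanned the RNA-binding protein gene Msi2 and Ccdc182 (chromosome 11, 88232972 to 88730020). The next was a 353 kb region of chromosome 8 that holds the start of Gins2 (120250509 to 120603362, 188 kb covered). The HoxC domain followed, with Hoxc4 to Hoxc12 and Smug1 (165 kb covered). Then came domains at Rbfox3 (chromosome 11, 125 kb covered), Zmiz1 (chromosome 14, 107 kb), Cstad, 1700001O22Rik and Ntmt1 (chromosome 2, 105 kb), and Ncor2 (chromosome 5, 104 kb). A domain on chromosome 9 (101 kb covered) held the starts of 14 genes: Cacna2d2, Tmem115, Cyb561d2, Nprl2, Zmynd10, Rassf1, Tusc2, Hyal2, Hyal1, Naa80, Hyal3, Ifrd2, Sema3b and Gnai2. HoxB (99 kb covered) and the neurogenic factor gene Ebf3 (chromosome 7, 96 kb) completed the first 10. Of the 100 domains with most covered bases, 82 met one of the top 100 built from replicate 2's list and 87 one of those built from replicate 1's. With a joining distance of 5 kb, 63 did.

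The strongest distal peaks lay mostly between protein-coding genes. The highest signal value, 68.6, was at an intronic peak of Bicral, 21.6 kb from its nearest start (chromosome 17, 46853882 to 46859628). The next, 67.7, was 21.05 kb long and lay 138 kb from Mef2c, over the long non-coding RNA gene C130071C03Rik (chromosome 13, 83713527 to 83734578). The other 8 were nearest to the starts of Chd2 (61.7, 14.9 kb away), Scyl1 (60.6, 28.2 kb), Kif13b (60.5, 55.9 kb), Cstad (58.5, 96.1 kb), Cypt12 (58.3, 156 kb), Sirt4 (57.7, 4 kb), Spen (54.9, 6.01 kb) and Zmiz1 (54.2, 79 kb). The peak nearest Scyl1 covered the start of the non-coding RNA gene Malat1, and those nearest Kif13b and Cypt12 covered starts of the microRNA host genes Mir124a-1hg and Mir124-2hg. Other non-coding starts lay within 1 kb of the peaks nearest Chd2 (1810026B05Rik), Sirt4 (Gm24265 and Gm24407), Spen (B330016D10Rik) and Zmiz1 (Gm26660).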

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

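The comparison with a deeper library and the matching on neighbouring starts were chosen after the result was seen. The replicated list held 13 peaks on 5 sequences outside the chromosomes used, which no comparison analysed. Their median signal value was 4.50 and their highest 43.2.

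Large parts of each replicate's list were missing from the other. A difference in depth is a candidate explanation that stays open, since no depth is known, and the 31.2% of replicate 2's peaks outside replicate 1's list is the observation itself and not a separate test of it. Weak peaks near the calling threshold are another that stays open: 99.8% of the 20000 strongest peaks of either list overlapped the other list, so what the replicates did not share was among the weaker peaks. No biological difference between the replicates is named by the labels, and none was tested.

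Of the 24 lists, 9 had more promoter peaks than other genes, among them progenitor, proneural, pan-neuronal and housekeeping genes, and CpG-rich promoters could give that, since they are acetylated in many tissues. Against genes matched on promoter CpG content, 5 of the 9 lists above other genes kept their call. They were the progenitor, proneural, pan-neuronal, Hox 1 to 9 and housekeeping lists. Of those 5, the Hox list allows no conclusion, since its neighbouring genes can share a peak and the draws treat genes as separate. For the rest of those 5 this argues against CpG content at the 5′ end of the gene as the whole cause. For the other 4 it stays open: the Notch share of 95% stood against 55.7% of other genes and 77.1% of matched genes, the retinoic acid and FGF share of 82.6% against 55.7% and 65.4%, the neural crest share of 86.4% against 55.7% and 72.1%, and the Wnt and BMP share of 79.3% against 55.7% and 84.4%. The matched test differed in its background and in its method, and which of these ended the calls was not tested. CpG content was measured only at the 5′ end of a gene, while a promoter peak could lie at any start. CpG content at other starts therefore stays open for all 9 lists, and the number of starts was not matched. For proneural genes the matched mean of 58.5% was near the 55.7% of other genes, so matching changed little there. Neighbouring Hox genes can share a promoter peak and are not separate units. A use of these genes by neural tissue was not tested, since no other tissue is in the data.

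Of the 24 lists, 11 had more distal peaks nearby than random lists, and sparse gene neighbourhoods could give that, since a gene far from others has more room for peaks that are not promoters. Against genes matched on the number of other starts within 50 kb, 10 of the 11 lists above random lists kept their call. For those outside the Hox clusters, this argues against the number of neighbouring starts as the whole cause. For the Hox lists no conclusion is drawn, since neighbouring genes count the same peaks and the draws treat genes as separate. The Hedgehog list, at 6.21 distal peaks per gene against 2.63 in random and 2.83 in matched lists, lost its call (adjusted permutation p = 0.0626). Neighbourhood stays open there. Peaks were counted within 50 kb of any start of a gene. The number of starts and the gene length were not matched, so both stay open for all 11 lists.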

How the results depend on the processing

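The replicate overlap (8 alternative values) and the promoter share of peaks (9) stayed above chance under every alternative run, with 100 shifts each. The number of lists called by promoter peaks (11) and by distal peaks (13) and the number of domains (3) stayed within 1.5 times the first count. Lists called by promoter peaks ranged from 13 with CpG-matched genes to 18, against 17, and those by distal peaks from 11 to 14, against 12. The overlap itself ranged from 36.6% of replicate 1's and 41.6% of replicate 2's peaks, with at least 50% of both peaks overlapping, to 84.0% and 85.2% among the 20000 strongest peaks of each list. The promoter share ranged from 13.4% with the pooled list to 50.9% among the 20000 strongest peaks. Settings added after seeing the data are the both-replicate rule, comprehensive gene models, neighbour matching and repeat masking.

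Other values moved, and the cause was not tested except where said. With at least 50% of both peaks overlapping, Spearman's rho was 0.806 and the share of replicated peaks supported by both replicates 51.2%. With 1 bp that share was 81.1%. Among the 20000 strongest peaks rho was 0.805, the promoter share of unshared peaks 25.8% in replicate 1 and 20.6% in replicate 2, and the Hox coverage 78% for HoxA, 54.9% for HoxB, 67.5% for HoxC and 66.4% for HoxD. With a −log10 q of at least 2 the promoter share of unshared peaks was 5.66% and 5.92%, and with at least 50% of the peak overlapping 6.58% and 6.62%. In the pooled list coverage was 58.1% for HoxB and 70.6% for HoxD, and with the both-replicate rule 55.9% for HoxB. Leaving out each replicate in turn gave 78.4% to 83.6% for HoxA, 55.6% to 55.8% for HoxB, 66.3% to 76.8% for HoxC and 64.9% to 66.9% for HoxD.

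With random windows matched on length only, 5 words were above 1 in place of 8, of which ETS CCGGAAG (2.31) and NRSE TTCAGCACC (1.24) were new. Sox ACAAAG lost its call (1.02), and 4 words turned below 1: TAATTA (0.691), ATGCAAAT (0.772), AGATAA (0.668) and CTATTT (0.634). Those windows had a GC content of 41.5%, against 49.1% in peaks. The Wnt and BMP promoter share of 79.3% changed sides against CpG-matched genes. Of 2340 values of single lists, words, genes and Hox parts under alternatives, 2167 did not change, 69 lost a call or peak, 82 gained one and 17 moved. No paired analysis was possible because the data hold a single group. Read depth is unknown, and its effect was not tested.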

Other observations

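The tests of base composition and of non-coding starts below were chosen after the values were seen. The genes in this paragraph were chosen after their values were seen, from the longest replicated peaks outside the Hox clusters. A peak of 45.7 kb on chromosome 3 (88196922 to 88242658) covered Mir9-1, one of 33.5 kb on chromosome 7 (79495706 to 79529251) covered Mir9-3 and its host gene, and one of 17.6 kb on chromosome 14 (64579053 to 64596668) covered Mir124a-1. Long peaks also lay at the start of the homeobox genes Lhx1 (14.9 kb) and Meis1 (14.8 kb).

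The strongest distal peaks may be starts of non-coding genes counted as distal, because only protein-coding starts defined promoters. Of the 100 distal peaks with the highest signal value, 27 had a lincRNA or microRNA start within 1 kb, against a mean of 8.71 and a highest of 22 in 10000 draws of other distal peaks of similar length (one-sided permutation p = 0.0001, the smallest the draws can give). Among the other 58264 distal peaks the share was 2.00%. The other 73 of the 100 had no lincRNA or microRNA start within 1 kb, and starts of other non-coding classes were not counted.

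The base composition of the words may account for part of the word ratios, since GATA and MEF2 words, taken for blood and muscle, were above 1 as well. The windows were matched on GC content but not on CpG. Of all words of 6 bases, CGCGGC (1.72) and CGTTAA (1.63) had higher ratios than TAATTA, and most of the 20 highest contained CpG. Of the 7 words of 6 bases above 1, 3 ranked in the top 10% of CpG-free words of the same base composition: CAGCTG (2 of 42), TAATTA (1 of 14) and TTGGCA (8 of 120). With only 3 of the 7 there, base composition remains a candidate explanation for the words as a set. ACAAAG ranked 3 of 25 and CTATTT 4 of 30, while GTTGCC (18 of 36) and AGATAA (14 of 30) lay near the middle. For the last pair, composition alone is consistent with the ratio.

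The name of the replicated list and the replicate lists did not match fully. Of its 73311 peaks, 13507 met the 50% rule in 1 replicate's list only and 724 in neither, so overlap with both deposited replicate lists was not required of every peak by that rule.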
